A study of Arabidopsis thaliana with 4 samples.

How the data were processed

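The material was intact Arabidopsis thaliana seedlings, aged 12 days, raised on MS medium containing 1% sucrose at 22 °C with 16 h of light and 8 h of darkness per day. Per the labels, RNA was extracted with Trizol and strand-specific mRNA libraries were made by dUTP marking. The 4 libraries comprised 2 of the Col wild type, 1 of the atprmt3 mutant and 1 of the rps2a2b mutant. Genotypes were read from the genotype label of each library.

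Per the submitters' processing notes, TopHat2 was used for alignment to the TAIR10 genome, HTSeq for counting and edgeR for expression, without versions. The deposited values are counts, whole numbers of reads (or read pairs) assigned to each of 33341 genes, without normalization. Read length, single or paired ends and the strand setting were not stated. Reads on no annotated gene made up 1.48%, 1.47%, 1.37% and 1.80% of all reads counted in Col library 1, Col library 2, atprmt3 and rps2a2b. Reads on more than 1 gene made up 3.18%, 3.26%, 2.25% and 2.38%, and reads with more than 1 alignment 6.97%, 7.16%, 6.74% and 7.13%. Gene names, positions and transcript sequences came from the TAIR10.1 reference annotation, which matched 33056 of the gene identifiers.

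Total counts on genes were 15646735 and 15637192 in the Col libraries, 18650053 in atprmt3 and 15194770 in rps2a2b. A count of 0 in a group allowed a level of up to 3 counts, which corresponds to a normalised read count (CPM) of 0.0993 in the Col libraries together, 0.159 in atprmt3 and 0.187 in rps2a2b. Intervals and floors cover counting error only, and grouped reads would widen them.

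The 2 Col libraries were compared with each other gene by gene. Over 20569 genes with at least 10 summed counts, the chi-square per gene was 0.989 (p = 0.858), where counting noise alone gives about 1. Only the 395 genes with at least 10000 summed counts exceeded it, at 1.32. Replicate plant cultures normally vary more than this, so the Col libraries were treated as a single sample and every genotype as n = 1. The spread between cultures of a genotype was therefore unknown for all 3 genotypes.

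Reads were treated as coming in groups. In each library fewer genes had 1 count than had 3 counts, for example 268 against 304 in Col library 1 and 203 against 314 in atprmt3. Between the mutant libraries the chi-square per gene rose from 5.68 for genes with 10 to 19 summed counts to 12.2 for genes with 640 to 1279, from 5.90 to 19.7 between Col library 1 and atprmt3, and from 6.27 to 26.0 between Col library 1 and rps2a2b. Groups of reads alone would keep it flat, so other variation was also present. A variance factor of 6.12, measured between the mutant libraries on genes with 10 to 99 summed counts, was applied to all read-sampling standard errors (SE), which corresponds to 5.12 extra reads per group. For the summed Col libraries the extra part was doubled, as both were taken to share their groups. The factor is an upper estimate, since it also holds real differences between the mutants, and whether reads are copies was not settled. It was chosen after the data had been examined. Values after ± are these SEs and hold no variation between plants.

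Differential expression was computed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 20937 genes. Counts were scaled by TMM factors, and quasi-likelihood tests were run on all 4 libraries with 3 groups and 1 residual degree of freedom. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Because the residual spread came from the Col libraries alone, the test compared the reads of libraries, not genotypes, and no p is given for single genes. The contrasts were atprmt3 against Col, rps2a2b against Col and rps2a2b against atprmt3. Log2 fold changes are TMM-scaled edgeR estimates, and CPM values use the same scaling, with the Col libraries summed. No paired analysis was possible because no library of a mutant belongs to a particular Col library.

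The procedure was tested on 4 fully simulated libraries, drawn around the mean Col levels at the real depths and without grouped reads. In them 200 genes were altered in the simulated atprmt3 library, taken only from well-counted genes. With counting noise alone, 57 of 100 genes altered 2-fold and 92 of 100 altered 4-fold were recovered, with 0 of 19732 unaltered genes called. When the mutant also varied with a biological coefficient of variation (BCV) of 0.2, 7662 of 19806 unaltered genes (38.7%) were called. Likelihood ratio tests with an assumed BCV of 0.2 then called 54 unaltered genes and recovered 26 and 90 of the altered ones.

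Expectations for unaltered mutants were simulated in 10 draws per setting, with the Col libraries shared by both contrasts, under counting noise, grouped reads or a BCV of 0.1, 0.2 or 0.4. The number of genes at least 2-fold apart was also simulated by expression class, in 20 draws. Simulated classes were set by the Col level alone and scaled to the observed number of genes. Observed classes used the mean over the 4 libraries, so only they can hold genes low in Col that pass through a high mutant level. The draws by expression class with a BCV were added after the data had been examined. The ratio of seed storage genes between the mutants was compared with 10000 random sets, each gene drawn from the 100 other genes nearest in summed count, also added after the data had been examined. Correlations between the mutants' fold changes are across genes, which are not independent replicates, so no p is given for them.

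Before the data were examined, 27 gene lists with 690 loci were fixed, as were the comparisons, the alternatives to be tried and the rule for naming genes. For each list the median log2 fold change was computed with its SE from 200 resamplings of the reads, and its percentile among 10000 random lists of equal size drawn from 40 expression bins. Percentiles are printed for some lists only. The percentile describes these libraries and is no test of the genotypes. The lists were the PRMT family, the RPS2 family, cytosolic 40S and 60S ribosomal proteins, plastid ribosomal proteins, nucleolar and ribosome biogenesis factors, the nucleolar stress regulator ANAC082, auxin response, photosynthesis, cell cycle, CDK inhibitors and DNA damage response, salicylic acid and defence, jasmonate response, abscisic acid with cold or drought response, heat shock, mitochondrial stress, flowering time, circadian clock, root markers, shoot meristem and leaf polarity, stomatal lineage, seed storage, flavonoid and anthocyanin, glucosinolate, iron deficiency, iron storage and phosphate starvation.

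Named genes were PRMT3, the RPS2 family and ANAC082 in every library. To these came, for each contrast, the 8 genes highest and the 8 lowest by log2 fold change among called genes with a gene symbol, a mean of at least 5 CPM and, in the mutant contrasts, a mutant level outside both Col libraries. Up to 4 called members of each list with the smallest adjusted p were also named, as were the 6 highest and 6 lowest genes called in the same direction in both mutants. Genes named outside this rule are identified as chosen after their values were seen.

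Sequence shared between genes was measured as the share of a transcript's 50-base stretches found at no other non-overlapping locus of the reference. A trend of fold change on transcript length and GC content was fitted and removed as an added alternative. Alternatives chosen beforehand were DESeq2 (1.42.0) size factors, upper-quartile factors, the DESeq2 Wald test, other low-count filters, a 2-fold minimum, assumed BCVs of 0.1, 0.2 and 0.4, fits with only Col and 1 mutant, and fold changes without each Col library. A likelihood ratio test with summed Col libraries at an assumed BCV of 0.2 was added after the data had been examined. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No set test and no regrouping of libraries was run, since each mutant had 1 library.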

Results

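Transcript levels were measured as read counts per gene in 4 mRNA libraries from whole seedlings. Of these, 2 came from Col, the wild type, 1 from atprmt3, a mutant of the arginine methyltransferase gene PRMT3, and 1 from rps2a2b, named for genes of the small-subunit ribosomal protein RPS2. The series title concerns how PRMT3 and RPS2B act on the assembly of pre-ribosomes and on nucleolar stress. Total counts on genes ranged from 15194770 in rps2a2b to 18650053 in atprmt3. The Col libraries differed from each other by no more than counting noise, so each genotype was represented by a single sample (n = 1). Differences are therefore between libraries, log2 fold changes carry read-sampling SEs, and no replicate error was available for a genotype. Between libraries of different genotypes even weakly expressed genes differed by several times counting noise, as reads that come in groups would, and the SEs include this.

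**Figure D1:**
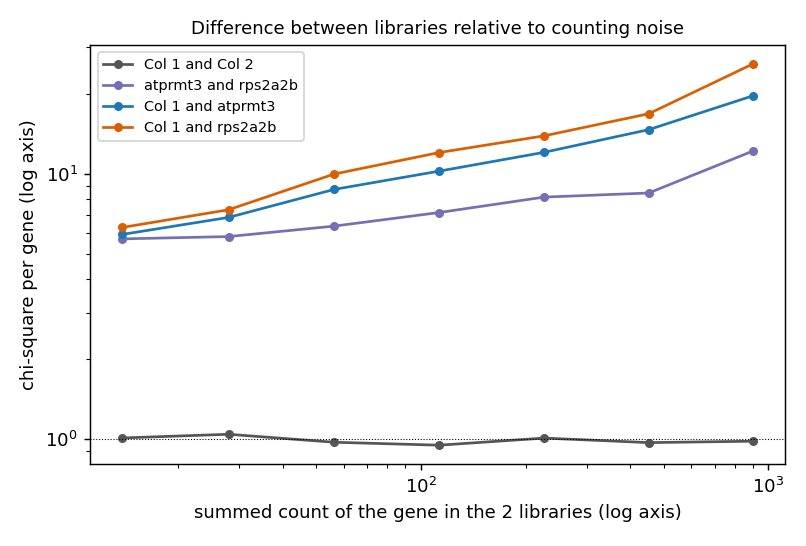
Chi-square per gene between pairs of libraries (log axis) by the summed count of the gene in the pair (log axis), where counting noise alone gives 1 (dotted line). The Col libraries stay near 1, and the 2 mutant libraries stand at 5.68 at 10 to 19 summed counts.

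The mutated genes were examined first. PRMT3 (AT3G12270, chromosome 3, 3910481 to 3913376) was lower in atprmt3 and not in rps2a2b. It had 237 and 254 counts in the Col libraries, 132 in atprmt3 and 315 in rps2a2b. Its level was 16.3 CPM in Col, 6.99 CPM in atprmt3 (95% counting interval 5.85 to 8.29) and 19.6 CPM in rps2a2b (17.5 to 21.9). The log2 fold changes against Col were -1.22 ± 0.38 and 0.27 ± 0.30, and PRMT3 reads were still present in atprmt3. RPS2A (AT1G58380, chromosome 1, 21688935 to 21690290) was lower in rps2a2b, at 10.4 CPM against 21.6 in Col, and higher in atprmt3, at 30.7 CPM. Its log2 fold changes were -1.05 ± 0.33 and 0.51 ± 0.24, and 72.3% of its sequence was unique in the reference.

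RPS2B (AT1G59359, chromosome 1, 21842190 to 21843819) and the copies AT1G58684 and AT1G58983 had 0 counts in every library. None of their 50-base stretches is unique (0%), so a count of 0 there gives no limit on their expression. The loci of RPS2A to RPS2D follow the standard nomenclature, as the labels name no loci. RPS2C (AT2G41840), the most abundant of the 3 measured members, stood at 0.22 ± 0.062 in atprmt3 and 0.13 ± 0.065 in rps2a2b, from 357 CPM in Col. RPS2D (AT3G57490) was higher in both, at 0.92 ± 0.31 and 1.02 ± 0.32, from 11.6 CPM. Over the 3 measured RPS2 genes the medians were 0.51 ± 0.20 in atprmt3, with 3 called higher and 0 lower (3 and 0 adjusted over the list alone), and 0.13 ± 0.061 in rps2a2b, with 2 called higher and 1 lower (2 and 1 adjusted over the list alone). ANAC082 (AT5G09330), a NAC transcription factor of the nucleolar stress response and the single member of its list, was slightly lower, at -0.28 ± 0.13 and -0.24 ± 0.14. It was called lower in both contrasts, also adjusted over the list alone, by edgeR but not by DESeq2, nor in rps2a2b with upper-quartile factors. Over the 9 PRMT genes the medians were 0.12 ± 0.13 in atprmt3 and 0.12 ± 0.13 in rps2a2b (0.069 without Col library 2), and PRMT3 was the lowest member in atprmt3. The family had 2 called higher and 2 lower (2 and 2 adjusted over the list alone) in atprmt3 and 1 called higher and 0 lower (1 and 0 adjusted over the list alone) in rps2a2b. Among them were PRMT4B (AT3G06930) at 0.46 ± 0.23, PRMT10 (AT1G04870) at 0.35 ± 0.23 and PRMT6 (AT3G20020) at -0.46 ± 0.33 in atprmt3, each called by edgeR and not by DESeq2.

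**Figure D2:**
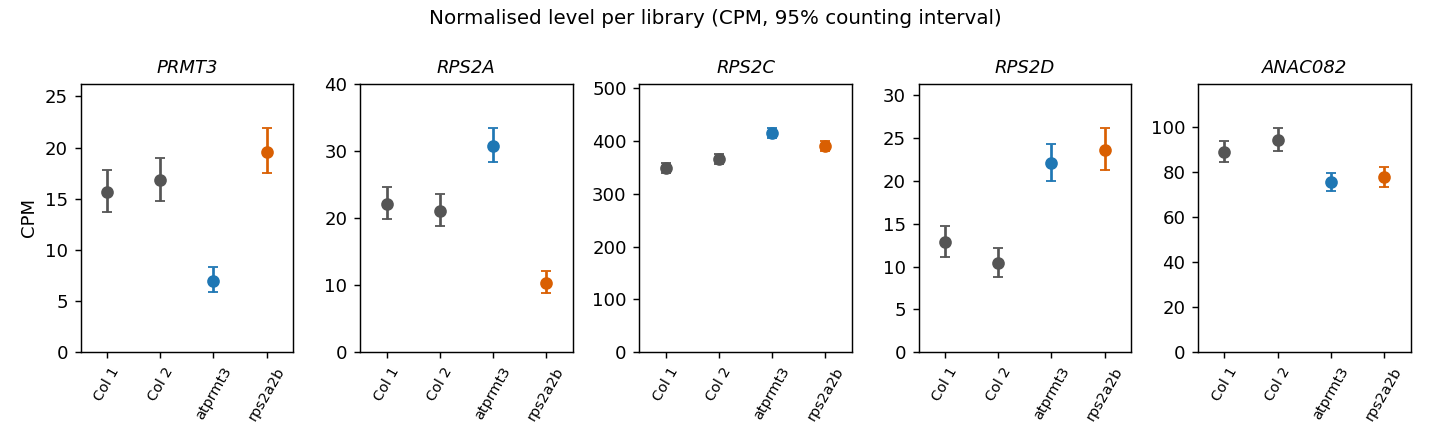
Normalised level (CPM, linear axis from 0) of PRMT3, RPS2A, RPS2C, RPS2D and ANAC082 in each of the 4 libraries, with 95% intervals of counting error alone, which grouped reads would widen. PRMT3 stands lowest in atprmt3 at 6.99 CPM and RPS2A lowest in rps2a2b at 10.4 CPM.

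The contrast of atprmt3 with Col asked which transcripts differ in seedlings with a mutated PRMT3. Transcripts of seed storage proteins and of flavonoid enzymes stood furthest above Col, with list medians of 3.71 ± 0.35 and 2.86 ± 0.50. Cytosolic ribosomal protein transcripts were higher as a class, with medians of 0.54 ± 0.024 for the small and 0.63 ± 0.020 for the large subunit, and cell cycle genes were higher at 0.65 ± 0.11. Auxin response genes were lower at -0.51 ± 0.11, circadian clock genes at -0.42 ± 0.13 and photosynthesis genes at -0.26 ± 0.014. Among 8624 genes with a mean of at least 20 CPM, 115 were at least 2-fold higher and 115 lower in atprmt3. For both directions together, simulated unaltered mutants gave 0.20 genes with grouped reads, 149 with a BCV of 0.2 and 2041 with a BCV of 0.4, and the spread between seedlings of a genotype was unknown.

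The 7 measured seed storage genes had 6 called higher and 0 lower (6 and 0 adjusted over the list alone) in atprmt3. The cruciferin genes CRU3 (AT4G28520) and CRA1 (AT5G44120) reached 270.2 and 341 CPM, against 13.4 and 26.0 in Col, or 4.34 ± 0.25 and 3.71 ± 0.18. The oleosin genes, for proteins of seed oil bodies, were OLEO1 (AT4G25140) at 5.35 ± 1.2 and OLEO2 (AT5G40420) at 2.94 ± 0.58. SESA1 (AT4G27140), a seed storage albumin, had 0 counts in Col and was at least 59.8-fold higher if reads are independent. Such bounds take 0 Col counts as at most 3, so reads in groups would lower them and widen the counting intervals. CRU2 (AT1G03880), also a cruciferin gene, had 0 counts in Col and in atprmt3. Without it, and with SESA1 at its bound, the median of the remaining genes was 4.03 in atprmt3. Other late embryogenesis genes were among the highest, with EM1 (AT3G51810) 113-fold above Col (95% counting interval 43.6 to 417, from 4 Col counts) and the dehydrin gene LEA (AT2G21490) 48.0-fold (20.13 to 150.1, from 5). The late embryogenesis gene M17 (AT2G41260) stood at 5.0 ± 1.21 and the beta-amylase gene BAM5 (AT4G15210) at 5.42 ± 1.08. MRD1 (AT1G53480) had 1 count in Col and was 659.6-fold higher (117.7 to 26110).

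All 13 measured flavonoid and anthocyanin genes lay above Col, with 13 called higher and 0 lower (13 and 0 adjusted over the list alone). CHS (AT5G13930), for chalcone synthase at the entry of the pathway, was at 0.85 ± 0.099, and the late enzyme genes were LDOX (AT4G22880) at 4.65 ± 1.25, DFR (AT5G42800) at 3.83 ± 0.92 and UGT75C1 (AT4G14090) at 2.86 ± 0.62. CHI (AT3G55120), for chalcone isomerase, was at 1.42 ± 0.32. MYBL2 (AT1G71030), a repressor of anthocyanin synthesis, was among the lowest genes at -2.09 ± 0.25, from 60.6 to 14.3 CPM.

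The 87 small-subunit ribosomal protein genes had 85 called higher and 1 lower (86 and 1 adjusted over the list alone), and the 121 large-subunit genes had 115 called higher and 1 lower (115 and 2 adjusted over the list alone). Both medians lay at percentile 100 of the random lists. Col library 2 against Col library 1 gave 0.0028 and 0.0083, but as 1 sample these libraries show read sampling only and no spread between samples. Examples were RPS6A (AT4G31700) at 0.96 ± 0.072, RPS3aA (AT3G04840) at 0.76 ± 0.064, RPS12C (AT2G32060) at 1.1 ± 0.16 and RPS11A (AT3G48930) at 0.85 ± 0.11 for the small subunit. The large subunit had RPL7aA (AT2G47610) at 0.80 ± 0.068, RPL13aB (AT3G24830) at 0.86 ± 0.090, RPL5A (AT3G25520) at 0.68 ± 0.060 and RPP0B (AT3G09200) at 0.70 ± 0.056. At least 2-fold higher were 8 small-subunit and 8 large-subunit genes, and 0 of either were 2-fold lower. With an assumed BCV of 0.2, few genes of either list passed singly, about the share that passed as higher among all genes. Nucleolar and ribosome biogenesis factors had a median of 0.23 ± 0.052, with 30 called higher and 7 lower (32 and 8 adjusted over the list alone) of 54. They included the nucleolin genes NUC2 (AT3G18610) at 2.77 ± 0.58 and NUC1 (AT1G48920) at 0.48 ± 0.062, the fibrillarin gene FIB2 (AT4G25630) at 1.14 ± 0.21 and the snoRNP protein gene NOP56 (AT1G56110) at 0.73 ± 0.10. Plastid ribosomal proteins had a median of 0.25 ± 0.025, with 29 called higher and 4 lower (29 and 4 adjusted over the list alone) of 38, among them PSRP5 (AT3G56910) at 0.68 ± 0.081, PRPL9 (AT3G44890) at 0.54 ± 0.097, PRPS13 (AT5G14320) at 0.41 ± 0.072 and PRPL13 (AT1G78630) at 0.37 ± 0.068. Removal of the trend on length and GC content lowered this median to 0.13.

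Cell cycle genes had 19 called higher and 1 lower (21 and 1 adjusted over the list alone) among 30. Examples were the B-type cyclins CYCB1;3 (AT3G11520) at 3.65 ± 0.99 and CYCB1;1 (AT4G37490) at 2.05 ± 0.58, the cytokinesis syntaxin KNOLLE (AT1G08560) at 0.95 ± 0.24 and CDC20.1 (AT4G33270) at 1.09 ± 0.22, of which 68.6% of the sequence was unique. CDK inhibitors and DNA damage genes had a median of 0.47 ± 0.16, with 8 called higher and 2 lower (9 and 2 adjusted over the list alone) of 11. TSO2 (AT3G27060) at 0.90 ± 0.14, for ribonucleotide reductase, PARP2 (AT4G02390) at 0.86 ± 0.40 and SOG1 (AT1G25580) at 0.54 ± 0.30 were above Col, and the CDK inhibitor SIM (AT5G04470) at -0.62 ± 0.32 was below.

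Photosynthesis genes had 13 called higher and 33 lower (13 and 33 adjusted over the list alone) among 47. Those lower included the light-harvesting antenna genes LHCB1.5 (AT2G34420) at -0.88 ± 0.012, from 14101 to 7662 CPM, LHCB2.1 (AT2G05100) at -1.24 ± 0.034 (77.3% unique sequence) and LHCA1 (AT3G54890) at -0.72 ± 0.022. The Rubisco small-subunit gene RBCS3B (AT5G38410) was higher at 0.26 ± 0.017.

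Auxin response genes had 2 called higher and 16 lower (2 and 16 adjusted over the list alone) among 25. They included the repressor IAA2 (AT3G23030) at -1.28 ± 0.23, the efflux carriers PIN3 (AT1G70940) at -0.70 ± 0.093 and PIN7 (AT1G23080) at -0.38 ± 0.093, and the conjugating enzyme GH3.5 (AT4G27260) at -0.57 ± 0.18. Circadian clock genes had 3 called higher and 9 lower (3 and 9 adjusted over the list alone) of 16, with LNK2 (AT3G54500) at -1.46 ± 0.20, PRR7 (AT5G02810) at -0.83 ± 0.11 and GI (AT1G22770) at -0.66 ± 0.084 below Col and CCR2 (AT2G21660) at 0.13 ± 0.022 above. Flowering time genes had a median of -0.24 ± 0.15, with 2 called higher and 6 lower (2 and 6 adjusted over the list alone) of 16. SOC1 (AT2G45660) at -1.66 ± 0.26, an activator of flowering, and SPL3 (AT2G33810) at -1.51 ± 0.66 were lower and SMZ (AT3G54990) at 1.85 ± 0.65, a repressor of flowering, was higher. FUL (AT5G60910), at 3 counts in atprmt3, was 12.5-fold lower (95% counting interval 4.08 to 62.3).

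Jasmonate response genes had a median of 0.59 ± 0.10, with 12 called higher and 1 lower (13 and 1 adjusted over the list alone) of 19, among them the biosynthetic genes LOX2 (AT3G45140) at 0.78 ± 0.041, AOC1 (AT3G25760) at 2.16 ± 0.27 and AOC2 (AT3G25770) at 1.15 ± 0.072 and the vegetative storage protein gene VSP2 (AT5G24770) at 0.42 ± 0.054. Salicylic acid and defence genes had a median of 0.77 ± 0.27 with members in both directions, 11 called higher and 2 lower (11 and 3 adjusted over the list alone) of 20. The glucanase gene PR2 (AT3G57260) was far below Col at -3.26 ± 0.86, from 9.70 to 1.01 CPM. NPR1 (AT1G64280) at -0.54 ± 0.23 was also below Col, and WRKY18 (AT4G31800) at 2.05 ± 0.80 and PR1 (AT2G14610) at 2.75 ± 1.52 were above. Abscisic acid, cold and drought genes had a median of 0.077 ± 0.069, with 11 called higher and 5 lower (11 and 5 adjusted over the list alone) of 25, including COR15A (AT2G42540) at 0.83 ± 0.049, RD22 (AT5G25610) at 0.60 ± 0.053, RD29A (AT5G52310) at 0.49 ± 0.057 and ERD10 (AT1G20450) at 0.38 ± 0.058. This median was 0.30 after removal of the trend on length and GC content.

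Phosphate starvation genes were higher, at a median of 1.17 ± 0.19 with 8 called higher and 0 lower (8 and 0 adjusted over the list alone) of 11. They included the non-coding RNA gene AT4 (AT5G03545) at 2.43 ± 0.48, the phosphatases PS2 (AT1G73010) at 2.41 ± 0.54 and PAP17 (AT3G17790) at 1.15 ± 0.21, and the transporter PHT1;4 (AT2G38940) at 1.19 ± 0.23. All 3 ferritin genes of iron storage were higher, at a median of 1.11 ± 0.14, with 3 called higher and 0 lower (3 and 0 adjusted over the list alone). They were FER1 (AT5G01600) at 1.13 ± 0.13, FER3 (AT3G56090) at 1.11 ± 0.21 and FER4 (AT2G40300) at 0.95 ± 0.25. Mitochondrial stress genes had a median of 0.66 ± 0.58, with 4 called higher and 1 lower (4 and 1 adjusted over the list alone) of 9. UGT74E2 (AT1G05680) at 2.46 ± 0.78, GSTU24 (AT1G17170) at 2.59 ± 0.89 and UPOX (AT2G21640) at 2.43 ± 0.82 were above Col, while AOX1D (AT1G32350) had 1 count in atprmt3 and was 16.9-fold lower (95% counting interval 2.78 to 690.5). Single genes far below Col also included the asparagine synthetase gene ASN1 (AT3G47340) at -2.25 ± 0.25, the metal reductase gene FRO4 (AT5G23980) at -2.4 ± 0.41, PGL5 (AT5G24420) at -2.24 ± 0.44, GolS4 (AT1G60470) at -2.19 ± 0.60, MAKR6 (AT5G52900) at -2.11 ± 0.52 and HFR1 (AT1G02340) at -2.15 ± 0.31, a transcription factor of phytochrome signalling.

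By the edgeR test, 5749 genes were called higher and 5487 lower of 20937. Simulated unaltered libraries with grouped reads gave 602 higher and 570.2 lower on average over 10 draws, and at most 2618 and 2519. With a BCV of 0.2 they gave 4181 and 4070.0, and with a BCV of 0.4 6708 and 6640.4, more than were observed. Among genes with a mean of at least 20 CPM, however, a BCV of 0.4 gave 2041 genes at least 2-fold apart, against 230 observed. That argues against a spread as large as 0.4 throughout such genes. The calls were 3494 by DESeq2 and 2165 with an assumed BCV of 0.2. With that BCV the photosynthesis list had 1 higher and 5 lower, auxin response 0 higher and 7 lower, cell cycle 7 higher and 0 lower, ribosome biogenesis 2 higher and 0 lower and flavonoids 9 higher and 0 lower. Clock genes had 0 higher and 2 lower, abscisic acid, cold and drought genes 1 higher and 0 lower, jasmonate response 4 higher and 0 lower, salicylic acid and defence 6 higher and 1 lower, flowering time 2 higher and 3 lower, mitochondrial stress 4 higher and 1 lower, phosphate starvation 7 higher and 0 lower and seed storage 6 higher and 0 lower. No plastid ribosomal protein, RPS2 family or CDK inhibitor and DNA damage gene passed, nor did ANAC082, while the PRMT family had 0 higher and 1 lower and ferritins 2 higher and 0 lower. Named genes that DESeq2 did not call in this contrast were RPS2A, PRMT4B, PRMT10, PRMT6, ANAC082, SOG1, PARP2, SIM, NPR1, PR1 and AOX1D, besides those of lists described later.

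**Figure D3:**
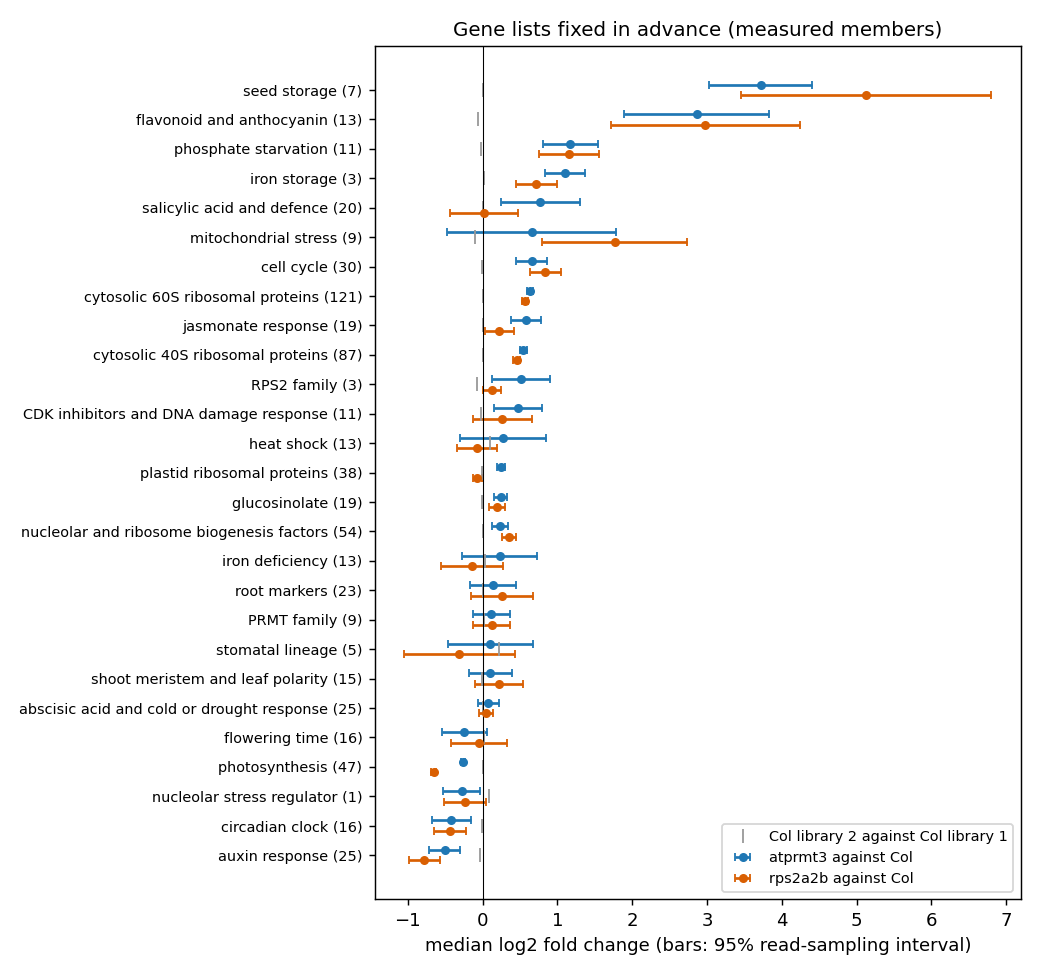
Median log2 fold change of each of the 27 gene lists against Col (horizontal axis) for atprmt3 (blue) and rps2a2b (orange), with bars of 95% read-sampling intervals and measured members in brackets. Grey ticks give the median between the Col libraries, which were treated as 1 sample and so show no spread between samples. Seed storage and flavonoid lists stand furthest right and the auxin response list furthest left, at -0.51 and -0.78.

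The contrast of rps2a2b with Col asked the same question for the RPS2 mutant. Seed storage transcripts stood furthest above Col, with a median of 5.12 ± 0.85, followed by flavonoid genes at 2.98 ± 0.65 and mitochondrial stress genes at 1.76 ± 0.49. Ribosomal protein transcripts were higher at 0.45 ± 0.027 and 0.57 ± 0.021 and cell cycle genes at 0.84 ± 0.11. Auxin response genes were lower at -0.78 ± 0.11, photosynthesis genes at -0.65 ± 0.016 and clock genes at -0.43 ± 0.11. Among the genes with a mean of at least 20 CPM, 134 were at least 2-fold higher and 153 lower. The simulated totals were 0.56 with grouped reads, 148 with a BCV of 0.2 and 2039 with a BCV of 0.4.

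All 7 measured seed storage genes were above Col, with 7 called higher and 0 lower (7 and 0 adjusted over the list alone). CRU3 and CRA1 reached 466 and 671 CPM, or 5.12 ± 0.24 and 4.69 ± 0.18. OLEO1 at 7.06 ± 1.2 and OLEO2 at 4.64 ± 0.56 were higher, and SESA1 was at least 152-fold higher if reads are independent. CRU2 had 48 counts in rps2a2b and was at least 30.1-fold higher under the same condition, and reads in groups would lower both bounds. With genes at 0 in Col set at their bounds the list median was 4.91. Of other late embryogenesis genes, EM1 was 842-fold above Col (95% counting interval 328 to 3093, from 4 Col counts) and LEA 298-fold (127 to 919, from 5). The embryonic protein gene ECP63 (AT2G36640) was at 6.15 ± 0.78, the vicilin-like gene PAP85 (AT3G22640) at 6.35 ± 1.2 and BAM5 at 6.18 ± 1.08. MRD1 was 489-fold higher (86.9 to 19370, from 1 count).

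Flavonoid and anthocyanin genes had 11 called higher and 0 lower (11 and 0 adjusted over the list alone) among 13, with CHS at 0.76 ± 0.10, DFR at 3.9 ± 0.92, UGT75C1 at 3.32 ± 0.62 and UGT79B1 (AT5G54060) at 5.24 ± 1.39. MYBL2 was lower at -2.66 ± 0.31. Mitochondrial stress genes had 5 called higher and 0 lower (5 and 0 adjusted over the list alone) of 9, with UPOX at 2.9 ± 0.81, UGT74E2 at 2.84 ± 0.78 and GSTU24 at 2.18 ± 0.93. NDB4 (AT2G20800), for an alternative mitochondrial NADH dehydrogenase, had 0 counts in Col and was at least 32.6-fold higher if reads are independent. Phosphate starvation genes had a median of 1.15 ± 0.20, with 8 called higher and 1 lower (9 and 1 adjusted over the list alone), and AT4 stood at 2.51 ± 0.48, PS2 at 2.66 ± 0.54, PHT1;4 at 1.36 ± 0.23 and PAP17 at 1.16 ± 0.21. The ferritin median was 0.72 ± 0.14, with 3 called higher and 0 lower (3 and 0 adjusted over the list alone), and FER1 was at 0.86 ± 0.13.

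Small-subunit ribosomal protein genes had 76 called higher and 3 lower (76 and 4 adjusted over the list alone) of 87 and large-subunit genes 111 called higher and 3 lower (112 and 3 adjusted over the list alone) of 121, with both medians at percentile 100. Examples were RPS6A at 0.77 ± 0.076, RPS8A (AT5G20290) at 0.53 ± 0.057, RACK1B (AT1G48630) at 1.08 ± 0.19, RPL19A (AT1G02780) at 0.67 ± 0.062, RPL24A (AT2G36620) at 0.96 ± 0.12 and RPL26A (AT3G49910) at 0.89 ± 0.073. At least 2-fold higher were 8 small-subunit and 7 large-subunit genes, and 1 and 0 were 2-fold lower. With an assumed BCV of 0.2, few genes of either list passed, about the share that passed as higher among all genes. Ribosome biogenesis factors had a median of 0.35 ± 0.048, 34 called higher and 2 lower (34 and 2 adjusted over the list alone), with NUC2 at 2.8 ± 0.58, NOP56 at 0.87 ± 0.10 and the snoRNP genes NOP58A (AT5G27120) at 0.85 ± 0.13 and GAR1 (AT3G03920) at 1.08 ± 0.14. Plastid ribosomal proteins had a median of -0.070 ± 0.028, with 9 called higher and 18 lower (9 and 18 adjusted over the list alone), including PRPL10 (AT5G13510) at -0.40 ± 0.069, PRPS9 (AT1G74970) at -0.54 ± 0.088, PRPL3 (AT2G43030) at -0.34 ± 0.064 and PRPS17 (AT1G79850) at -0.33 ± 0.060. Without correction the median stood at percentile 80.6 of the random lists, so most lists of similar expression lay lower. It was -0.16 after removal of the trend on length and GC content.

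Cell cycle genes had 24 called higher and 1 lower (25 and 1 adjusted over the list alone), including CYCB1;3 at 2.81 ± 1.03, CYCB1;1 at 1.9 ± 0.59, CDC20.1 at 1.29 ± 0.23 and the replication clamp gene PCNA2 (AT2G29570) at 0.92 ± 0.30. CDK inhibitor and DNA damage genes had a median of 0.26 ± 0.20, with 4 called higher and 0 lower (4 and 0 adjusted over the list alone), among them PARP2 at 1.33 ± 0.39, BRCA1 (AT4G21070) at 0.98 ± 0.41 and TSO2 at 0.91 ± 0.14.

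Photosynthesis genes had 4 called higher and 42 lower (4 and 42 adjusted over the list alone), with LHCB1.5 at -1.19 ± 0.014, LHCA1 at -1.0 ± 0.024, LHCA2 (AT3G61470) at -0.62 ± 0.022 and the photosystem I gene PSAD1 (AT4G02770) at -0.73 ± 0.027. Auxin response genes had 2 called higher and 17 lower (3 and 17 adjusted over the list alone), with PIN3 at -0.78 ± 0.10, PIN7 at -0.50 ± 0.099, GH3.5 at -0.81 ± 0.19 and the response factor ARF7 (AT5G20730) at -0.67 ± 0.13. SAUR20 (AT5G18020), another auxin-responsive gene, was at -2.12 ± 0.70. Clock genes had 0 called higher and 9 lower (0 and 9 adjusted over the list alone), with LNK2 at -1.67 ± 0.22, LNK1 (AT5G64170) at -0.64 ± 0.16 and GI at -0.52 ± 0.086. Flowering time genes had a median of -0.046 ± 0.19, which was 0.074 without Col library 2, with 4 called higher and 6 lower (4 and 6 adjusted over the list alone). SOC1 was lower at -2.13 ± 0.32, SMZ higher at 2.19 ± 0.65, SVP (AT2G22540) at -0.35 ± 0.12 lower and MAF3 (AT5G65060) at 1.3 ± 0.60 higher, and FUL was 10.6-fold lower at 3 counts (95% counting interval 3.47 to 53.1).

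Jasmonate response genes had a median of 0.22 ± 0.10, 12 called higher and 2 lower (12 and 2 adjusted over the list alone), with AOC1 at 1.79 ± 0.28 and LOX2 at 0.60 ± 0.043. Salicylic acid and defence genes had a median of 0.015 ± 0.23, within its SE and at -0.011 without Col library 1, with 6 called higher and 4 lower (6 and 4 adjusted over the list alone). PR2 was at -3.81 ± 1.09, CYP71A13 (AT2G30770) at 2.06 ± 0.96 was higher, and SARD1 (AT1G73805) was 15-fold higher from 4 Col counts (95% counting interval 5.33 to 58.5). PCC1 (AT3G22231), with 69.2% unique sequence, was 12.8-fold lower at 4 counts (4.83 to 47.8). Abscisic acid, cold and drought genes had a median of 0.050 ± 0.049 (0.075 without Col library 1 and 0.032 without Col library 2), with 9 called higher and 6 lower (11 and 6 adjusted over the list alone). RD29B (AT5G52300) at 0.89 ± 0.11 and RAB18 (AT5G66400) at 0.63 ± 0.084 were higher and COR15B (AT2G42530) at -0.51 ± 0.11 and ADH1 (AT1G77120) at -0.54 ± 0.14 lower. Single genes far below Col also included PGL5 at -2.4 ± 0.50, HFR1 at -2.33 ± 0.35, the squamosa promoter-like factor SPL11 (AT1G27360) at -2.11 ± 0.69 and the chlorophyllase gene CLH2 (AT5G43860) at -2.08 ± 0.72.

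By the edgeR test, 5580 genes were called higher and 5415 lower, against means of 569 and 556 and maxima of 2442 and 2356 in simulated libraries with grouped reads. With a BCV of 0.2 the simulated means were 3905 and 3814, and with a BCV of 0.4 they were 6529 and 6493, more than were observed. Again, a BCV of 0.4 gave far more genes at least 2-fold apart at a mean of at least 20 CPM, 2039 against 287 observed. The calls were 3608 by DESeq2 and 2427 with an assumed BCV of 0.2. With that BCV the photosynthesis list had 1 higher and 9 lower, auxin response 1 higher and 9 lower, cell cycle 9 higher and 0 lower, ribosome biogenesis 2 higher and 0 lower and flavonoids 9 higher and 0 lower. Clock genes had 0 higher and 1 lower, abscisic acid, cold and drought genes 1 higher and 0 lower, jasmonate response 4 higher and 1 lower, salicylic acid and defence 5 higher and 2 lower, flowering time 3 higher and 2 lower, mitochondrial stress 5 higher and 0 lower, phosphate starvation 6 higher and 0 lower and seed storage 7 higher and 0 lower. No plastid ribosomal protein, PRMT family or ferritin gene passed, nor did ANAC082, while the RPS2 family had 1 higher and 0 lower and CDK inhibitor and DNA damage genes 1 higher and 0 lower. Named genes that DESeq2 did not call in this contrast were RPS2C, ANAC082, PRMT4B, SOG1, BRCA1 and MAF3, besides those of lists described later.

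The mutant libraries were also set against each other, where the fold changes do not involve Col. In rps2a2b, seed storage genes stood above atprmt3, and photosynthesis and plastid ribosomal protein genes stood below. The seed storage median was 1.35 ± 0.26, with 6 called higher and 0 lower (6 and 0 adjusted over the list alone) of 7 and 3 higher and 0 lower at an assumed BCV of 0.2. The photosynthesis median was -0.31 ± 0.0092, with 0 called higher and 43 lower (1 and 43 adjusted over the list alone) of 47. The plastid ribosomal protein median was -0.31 ± 0.023, with 0 called higher and 33 lower (0 and 34 adjusted over the list alone) of 38. At an assumed BCV of 0.2 the photosynthesis list had 0 higher and 0 lower and the plastid ribosomal proteins 0 higher and 0 lower, and no ribosome biogenesis or cell cycle gene passed. Among genes with a mean of at least 20 CPM, 29 were at least 2-fold higher and 25 lower. The simulated totals were 0.20 with grouped reads, 146 with a BCV of 0.2 and 2041 with a BCV of 0.4. The observed total of 54 was below both BCV settings, which argues against a spread as large as 0.4 between these libraries throughout such genes. How far the single Col sample deviates is not bounded by this contrast.

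The highest genes were PAP85 at 3.21 ± 0.40, EM1 at 2.9 ± 0.23, LEA at 2.63 ± 0.32, LEA7 (AT1G52690) at 2.41 ± 0.22, ECP63 at 2.29 ± 0.21 and BETA-TIP (AT1G17810) at 2.23 ± 0.44, a tonoplast aquaporin gene. ICL (AT3G21720), for isocitrate lyase of the glyoxylate cycle, was lower in atprmt3 than in Col and higher in rps2a2b. It stood at 160.2 CPM in Col, 68.1 in atprmt3 and 362 in rps2a2b, with log2 fold changes of -1.23 ± 0.12 and 1.18 ± 0.084 against Col. It was the only gene with a mean of at least 5 CPM at least 2-fold from Col in opposite directions. MLS (AT5G03860), for malate synthase of the same cycle, stood at 7.32, 16.2 and 80.7 CPM, a difference of 2.32 ± 0.23 between the mutants. RPS2A was among the lowest genes at -1.56 ± 0.31, with PRF1 (AT2G19760) at -1.73 ± 0.25, a profilin gene, CSD2 (AT2G28190) at -1.41 ± 0.35, a copper/zinc superoxide dismutase gene, GRP5 (AT3G20470) at -2.14 ± 0.58, CYP735A2 (AT1G67110) at -1.86 ± 0.74, a cytokinin hydroxylase gene, RGF6 (AT4G16515) at -1.78 ± 0.60, ACD6 (AT4G14400) at -1.65 ± 0.58 and LBD21 (AT3G11090) at -1.55 ± 0.57. PRMT3 was higher at 1.48 ± 0.37.

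Ribosome biogenesis factors differed by 0.14 ± 0.035, with 11 called higher and 3 lower (12 and 3 adjusted over the list alone), and cell cycle genes by 0.032 ± 0.076, with 3 called higher and 2 lower (3 and 2 adjusted over the list alone). The 40S and 60S lists differed by -0.097 ± 0.020 and -0.071 ± 0.015. By the edgeR test 2645 genes were called higher and 2671 lower in rps2a2b. The calls were 112 (47 higher and 65 lower) with upper-quartile factors, 1302 without a filter on low counts and 597 (228 and 369) by DESeq2. RPS2A, BETA-TIP, CSD2, GRP5, ACD6 and RGF6 were not called with upper-quartile factors, and CYP735A2 and LBD21 neither with these nor by DESeq2.

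The mutants were finally compared for genes on the same side of Col. Among genes with a mean of at least 5 CPM, 308 were at least 2-fold higher and 154 at least 2-fold lower in both mutants, and 1 was in opposite directions. The products of the separate counts give 14.1 and 8.56 for unrelated sets, but sharing Col raises both numbers. Simulated unaltered mutants gave 24.1 and 5.86 with grouped reads, 27.3 and 11.5 with a BCV of 0.2 and 758 and 516 with a BCV of 0.4. Simulated genes were selected by their Col level and observed genes by the mean of all libraries, which favours the observed number higher in both. At a mean of at least 20 CPM, the counts were 87 and 73, against products of 1.79 and 2.04 and simulated values of 13.3 and 5.87 with a BCV of 0.2 and 429 and 289 with a BCV of 0.4. The highest in both were SESA1, MRD1, EM1, LEA, BAM5 and OLEO1. The lowest were PR2, PGL5, HFR1, MYBL2, ASN1 at -2.25 ± 0.25 and -2.02 ± 0.25, and FRO6 (AT5G49730), a ferric reductase gene of leaves, at -2.06 ± 0.15 and -2.07 ± 0.17.

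By the edgeR test, 3724 genes were called higher in both and 3534 lower in both, against 1532 and 1419 from the products of the separate counts, and 355 were called in opposite directions. Simulated unaltered mutants that share Col gave 208 and 181 with grouped reads, 1969 and 1949 with a BCV of 0.2 and 3681 and 3747 with a BCV of 0.4, on average over 10 draws. Genes both called and at least 2-fold apart numbered 1139 and 503, against 77.4 and 53.5 with grouped reads and 986 and 692 with a BCV of 0.4. The Pearson correlation of the log2 fold changes across 20937 genes was 0.707, Spearman's rho 0.660 and the covariance 1.25. Both contrasts share Col, which alone gives a correlation. Simulated unaltered mutants gave r of 0.536 and a covariance of 0.721 with grouped reads, and r of 0.483 and a covariance of 0.391 with a BCV of 0.4. Grouped reads and a BCV were not simulated together, so either value alone may understate the covariance of unaltered mutants. In the 8624 genes with a mean of at least 20 CPM, r was 0.809 and the covariance 0.213. Simulated unaltered mutants gave r of 0.513 and a covariance of 0.018 with grouped reads, and 0.501 and 0.366 with a BCV of 0.4. There the SD of the log2 fold changes was 0.50 in atprmt3 and 0.53 in rps2a2b, and 0.32 between the mutants.

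**Figure D4:**
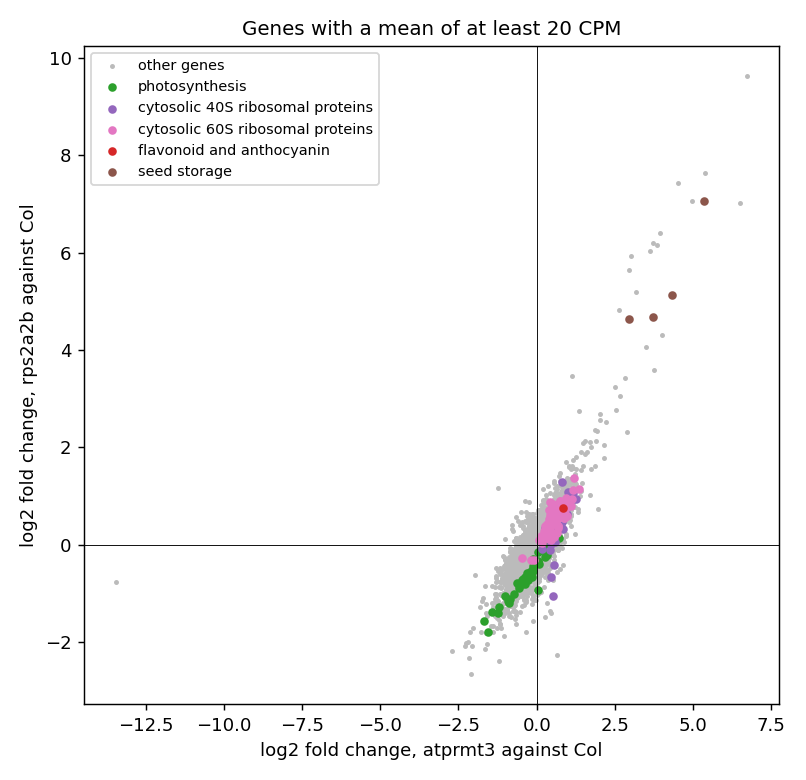
Log2 fold change against Col of the 8624 genes with a mean of at least 20 CPM, in atprmt3 (horizontal axis) and rps2a2b (vertical axis), with members of 5 gene lists in colour. Most genes lie along the rising diagonal (r = 0.809, where simulated unaltered mutants sharing Col gave 0.513 with grouped reads), and the isolated point at the left is AT2G06845, chosen after its values were seen, with 0 counts in atprmt3.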

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

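Of the tests reported here, those of the state, growth stage or harvest of the Col sample were chosen after the result was seen, as were dividing the seed storage chi-squares by the read group factor and comparing them with other genes.

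Outside the counts on genes, reads on no annotated gene made up 1.797% of all reads counted in rps2a2b, above the Col libraries (1.48% and 1.47%) and atprmt3 (1.37%). No explanation was tested.

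Cytosolic ribosomal protein transcripts were higher in both mutant libraries. A bias of length or GC content between libraries is argued against as the whole cause, since the smaller of the mutants' medians over 208 genes stayed at 0.4388 after that trend was removed, from 0.52. The median also stood at percentile 100 among random lists matched on length, GC content and expression in both mutants. Reads shared between copies are argued against by the 188 members with at least 95% unique sequence. Their medians were 0.599 in atprmt3 and 0.5222 in rps2a2b, against 0.594 and 0.522 over all 208 genes. The state of the single Col sample cannot be told apart from an effect of the mutations, as there was 1 independent Col sample.

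Seed storage transcripts summed to 42.8 CPM in Col, 663.5 in atprmt3 and 1295 in rps2a2b. A single seed-derived source carried in different amounts would keep the genes in 1 ratio between the mutants. This remains open. The ratio differed beyond read sampling, with a chi-square of 6.969 per degree of freedom after division by the read group factor. That bound left out the spread between samples, and random sets of other genes with similar counts gave a median of 2.62, which places the seed storage value at percentile 85.7 of them. Reads of the mutant libraries leaking into Col would lower the difference, not create it. Whether such reads account for the Col counts was not settled. The planned chi-squares for 1 fixed share exceeded counting error, at 107 on 5 degrees of freedom for atprmt3 and 98.67 on 6 for rps2a2b. That criterion took reads as independent. After division by the read group factor the smaller chi-square was 1.463 per degree of freedom. Col counts were 4.56% of the mutants' counts for CRA1 but 0.193% for EM1, which was named for its high fold change. Delayed seedling development may also account for the pattern as a biological explanation, which was not tested.

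Both mutant libraries lay on the same side of Col for 75.7% of genes, where simulated unaltered mutants sharing Col gave 66.5% with grouped reads and with a BCV of 0.4. A length or GC trend shared by the mutants is argued against, as r was 0.707 after its removal. Independent variation of 3 samples sharing Col remains open although the observed r of 0.7068 exceeded every simulated value, the criterion fixed beforehand. That criterion was wrong because a Col sample that deviates more than the simulated ones raises r further. Growth stage or harvest of the Col sample cannot be told apart from shared effects of the mutations either, since a chi-square of 0.9894 per gene leaves the Col libraries as 1 sample.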

How the results depend on the processing

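Summed Col libraries and removal of the length and GC trend were alternatives chosen after the data had been seen, and the others were planned. Numbers of called genes are given for atprmt3, rps2a2b, the direct contrast and both mutants in the same direction. They were within 1.5 times the reported values of 11236, 10995, 5316 and 7258 with DESeq2 size factors, at least 1 CPM in 2 libraries and, for the mutant contrasts, only Col and that mutant. Upper-quartile factors and no filter moved only the direct contrast, to 112 and 1302. A 2-fold minimum gave 2846, 3050, 1353 and 1642, as its construction requires. DESeq2 gave 3494, 3608, 597 and 2254. An assumed BCV of 0.1 gave 6612, 6692, 2105 and 3848, of 0.2 gave 2165, 2427, 646 and 1254, and of 0.4 gave 653, 771, 92 and 416. Summed Col libraries at 0.2 gave 1690, 1894, 646 and 984. The assumed spread explains the decline with BCV, and otherwise the cause was not tested. Without a Col library no residual degree of freedom was left, so no counts were run.

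The correlation between the mutants was 0.674 and 0.675 with a different Col library in each contrast. The covariance did not fall there, at 1.2483 and 1.2496 against 1.2473. Since the Col libraries were taken as 1 sample, this setting cannot show what independent controls would give. The correlation was 0.794 with at least 1 CPM in 2 libraries and 0.707 without the length and GC trend. Of 54 list medians, all 54 kept their sign with both other scalings, and 52 without each Col library and without the trend. Medians moved by more than their read-sampling error, for atprmt3 and rps2a2b, when the trend was removed: 40S 0.40 and 0.38, 60S 0.50 and 0.50, plastid ribosomal proteins 0.13 and -0.16, photosynthesis -0.33 and -0.69, for atprmt3 alone, abscisic acid, cold and drought 0.30, shoot meristem 0.27 and iron storage 0.95, and for rps2a2b alone circadian clock -0.26. Upper-quartile factors did so for photosynthesis, at -0.22 and -0.63, and, in atprmt3, for 40S at 0.58, 60S at 0.67 and plastid ribosomal proteins at 0.28. Leaving out 1 Col library moved no median by more than its error, but libraries that differ by counting noise alone could hardly show otherwise. Moves over 1.5 times were, in atprmt3, heat shock 0.044 to 0.32 and stomatal lineage -0.031 to 0.26, and, in rps2a2b, the PRMT family 0.069, salicylic acid -0.011 to 0.061, abscisic acid 0.032 to 0.075, heat shock -0.14 to 0.0029, flowering time -0.12 to 0.074 and iron deficiency -0.056 to -0.013. Removing the trend moved others over 1.5 times within their errors, such as ANAC082 at -0.18 and -0.16. The cause was not tested. The scalings moved the median gene by at most 0.034. Of 246 comparisons of 170 named genes, 245 were called. Of these, 206 stayed called by DESeq2, 245 with its size factors and 234 with upper-quartile factors, and the rest kept their direction. The remaining comparison, PRMT3 in rps2a2b, stayed uncalled. All 230 tested without each Col library kept their direction, which for the same reason is no check against another Col sample. Depth limits weakly expressed genes. At a mean of at least 5 CPM, simulated grouped reads alone gave 122 genes at least 2-fold apart in atprmt3, 152 in rps2a2b and 124 in the direct contrast, and at 20 CPM fewer than 1.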

Other observations

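The tests of read groups and of AT2G06845 were chosen after the result was seen, and that of the mutated loci was planned.

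Root markers had medians of 0.14 ± 0.16 in atprmt3 and 0.26 ± 0.21 in rps2a2b, with 8 called higher and 5 lower (8 and 5 adjusted over the list alone) and 9 called higher and 6 lower (9 and 6 adjusted over the list alone) of 23. The beta-glucosidase gene PYK10 (AT3G09260) stood at 0.47 ± 0.023 in rps2a2b, the root hair gene PRP3 (AT3G62680) at 1.21 ± 0.17 and its regulator RHD6 (AT1G66470) at 2.3 ± 1.01, while SCR (AT3G54220), which patterns the endodermis, was lower at -0.75 ± 0.19. EXPA18 (AT1G62980), a root hair expansin gene, was at 1.5 ± 0.68 in atprmt3. Shoot meristem and leaf polarity genes had medians of 0.10 ± 0.15 and 0.22 ± 0.17, with 5 called higher and 2 lower (5 and 2 adjusted over the list alone) and 9 called higher and 0 lower (9 and 0 adjusted over the list alone) of 15. The boundary gene CUC3 (AT1G76420) was at 2.14 ± 1.39 and 2.48 ± 1.38, KNAT1 (AT4G08150) at 0.55 ± 0.26 and 0.67 ± 0.26, AS2 (AT1G65620) at 1.35 ± 0.65 in atprmt3 and KNAT6 (AT1G23380) at 0.84 ± 0.50 in rps2a2b. Stomatal lineage genes had medians of 0.11 ± 0.29 and -0.31 ± 0.38, within their SEs, and the former was -0.031 without Col library 1. There were 2 called higher and 1 lower (2 and 1 adjusted over the list alone) and 1 called higher and 1 lower (1 and 2 adjusted over the list alone) of 5, with FAMA (AT3G24140) at -0.31 ± 0.21 and -0.67 ± 0.24, SPCH (AT5G53210) at 0.83 ± 0.43 in rps2a2b, and TMM (AT1G80080) at 0.36 ± 0.25 and MUTE (AT3G06120) at 1.83 ± 1.05 in atprmt3.

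Glucosinolate genes had medians of 0.24 ± 0.045 and 0.19 ± 0.056, with 14 called higher and 2 lower (14 and 3 adjusted over the list alone) and 10 called higher and 3 lower (10 and 5 adjusted over the list alone) of 19. BCAT4 (AT3G19710), of methionine chain elongation, was at 0.55 ± 0.076 and 0.52 ± 0.079, GGP1 (AT4G30530) at 0.71 ± 0.11 and 0.82 ± 0.12, and CYP79B3 (AT2G22330), of the indolic branch, at -0.75 ± 0.15 and -0.68 ± 0.15. Iron deficiency genes had medians of 0.23 ± 0.26 and -0.14 ± 0.21 (the latter -0.013 without Col library 1 and -0.056 without Col library 2), with 4 called higher and 2 lower (4 and 2 adjusted over the list alone) and 2 called higher and 3 lower (2 and 2 adjusted over the list alone) of 13. The iron transporter gene IRT1 (AT4G19690) was at 1.86 ± 0.59 in atprmt3 and -0.22 ± 0.78 in rps2a2b, the reductase gene FRO2 (AT1G01580) at 1.23 ± 0.62 and -0.78 ± 0.87, and the regulator gene BTS (AT3G18290) at -0.48 ± 0.095 and -0.36 ± 0.097. Heat shock genes had medians of 0.27 ± 0.29 and -0.074 ± 0.14, the former 0.044 without Col library 1 and the latter 0.0029 without Col library 2, with 5 called higher and 5 lower (5 and 5 adjusted over the list alone) and 2 called higher and 1 lower (2 and 1 adjusted over the list alone) of 13. HSP70 (AT3G12580) was at -0.47 ± 0.10 and -0.014 ± 0.099, HOP3 (AT4G12400) at -0.84 ± 0.27 and -0.074 ± 0.25, and ROF2 (AT5G48570) at -0.64 ± 0.19 and -0.38 ± 0.19. At an assumed BCV of 0.2 these lists had, in atprmt3 and rps2a2b, 4 higher and 0 lower and 4 higher and 0 lower for root markers, 2 higher and 0 lower and 3 higher and 0 lower for shoot meristem, 1 higher and 0 lower and 0 higher and 0 lower for stomatal lineage, 2 higher and 0 lower and 0 higher and 0 lower for iron deficiency, 2 higher and 0 lower and 1 higher and 0 lower for heat shock and none for glucosinolates.

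Several reads per starting molecule, as copies made in amplification, are a candidate explanation for the few genes with 1 count, which remains open. Copies would leave the chi-square per gene nearly flat with expression, within 1.5 times, and variation in proportion to expression would raise it about as much as the counts. From genes with 20 to 39 summed counts to genes with about 8 times as many it rose 1.408 times between the mutant libraries, but 1.758 times between Col library 1 and atprmt3 and 1.899 times between Col library 1 and rps2a2b. Between the Col libraries it stayed near 1 (1.04 and 1.01).

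Variants or insertions carried near the mutated loci could alter neighbouring genes. Among genes with a mean of at least 5 CPM within 1 Mb of PRMT3, 18 of 359 (5.01%) were at least 2-fold from Col in atprmt3, against 4.97% elsewhere. Near RPS2A 5 of 227 (2.2%) were so in rps2a2b, against 5.91%. Without this limit on expression, added after the result was seen, the shares were 16.0% against 15.2% near PRMT3 and 11.2% against 16.3% near RPS2A. With the limit, the odds ratios were 1.01 (95% interval 0.588 to 1.632) near PRMT3 and 0.359 (0.115 to 0.853) near RPS2A. The highest of the upper 95% bounds of the odds ratios was 1.632, which argues against a concentration of such genes there. The cause of the lower share near RPS2A was not tested.

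AT2G06845 (chromosome 2, 2753443 to 2756008), annotated as related to beta-galactosidase and chosen after its values were seen, had 1285 and 1301 counts in the Col libraries, 0 in atprmt3 and 809 in rps2a2b. The overlapping non-coding locus AT2G05015 had 78, 68, 0 and 86. Of 5970 genes with at least 1000 Col counts, the number of others with 0 counts in a mutant library was 0, which makes chance loss of reads in 1 library unlikely. A deletion or rearrangement in the atprmt3 line is a hypothesis that these counts cannot test. Of genes with 0 Col counts, 95 had at least 20 counts in atprmt3, 115 in rps2a2b and 56 in both. With 0 counts in a mutant and at least 40 in Col there were 10, 20 and 1, the last being the phosphoenolpyruvate carboxylase gene PPC4 (AT1G68750), also chosen after its values were seen.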
